A study of Mus musculus with 6 samples.

How the data were processed

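Transcript levels were measured in the hypothalamus of male C57BL/6J mice aged 16 weeks on 6 single-colour Cy3 arrays, 2 per genotype. TrspFF mice carry floxed alleles of Trsp and form the control group. Trsp-RIPKO and Trsp-Ins1KO mice carry the floxed alleles together with RIP-Cre or Ins1-Cre. The labels name the arrays of a genotype by replicate number and do not say whether each came from a separate animal. Per the labels, total RNA was labelled with a low-input kit and hybridised to whole-genome mouse arrays, and Agilent Feature Extraction 10.7.3.1 read the scans. Per the file headers, the scanner files hold the intensity of each spot after background subtraction (the processed signal) with its quality flags, and the array annotation follows mouse build mm9. The deposited value table holds log2 values for the same probes, centred so that the median of each probe over the 6 arrays is 0. How the authors scaled the arrays and combined spots in that table is not given in the sources used here.

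All values come from the scanner files. Of 43020 spots that are not controls, those of the same probe were averaged after leaving out spots with a quality flag, which gave 39429 probes; 118 probes with only flagged spots on some array were left out of the tests. The log2 processed signal minus the 75th percentile (log2) of its array is the level used throughout, so a level of 0 equals that percentile. A probe was kept when it was well above background on both arrays of at least 1 group, which left 28156 probes. Gene symbols were assigned through the transcript accessions of the probes and a gene table of build GRCm38.p6: 26055 of 39429 probes (66.1%) received a symbol and 13374 did not. The brightest kept probe stood for each gene, and probes without a symbol were tested under their accession or probe name. This gave 22862 tested genes, 15084 with a usual symbol and 7264 under an accession or probe name; 4402 genes had several kept probes.

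Each of the 3 pairs of genotypes was compared with limma 3.58.1 in R 4.3.3 (lmFit on all 6 arrays and eBayes, with Benjamini-Hochberg adjustment over all tested genes at 0.05). The residual and prior degrees of freedom came to 4.87, and the median standard error of a difference was 0.127 (log2). Errors given with a difference are moderated standard errors, and all differences are log2 of the group named earlier minus the other. The p-values measure only the spread between these arrays, which may be technical where arrays do not come from separate animals. For a gene whose tested probe was not well above background on any array of a group, the difference is given as a bound: each of its arrays takes the faintest signal called well above background on that array, or its own signal where that is higher, and the result is written as "at least N-fold". An adjusted p given with a bound is that of the fitted difference, which uses the faint signals as measured. It does not test the bound. Labels and file headers were read with jsonlite 2.0.0.

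38 gene lists were written before the data were examined, together with the comparisons, thresholds, filters, alternatives and rule for naming genes; 1 further list of sex-linked genes served as a check. They cover selenium biology, antioxidant defence, stress responses, neuropeptides, hormone signalling, energy metabolism, neuron and glial types, vascular cells and tissue outside the hypothalamus. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 38 lists, and again with an estimated correlation and with fry. Members of lists were also adjusted over the list alone. Genes named in the text are those with a usual symbol and the 12 largest rises and 12 largest falls among those past the threshold. Where fewer than 8 passed in a direction, genes with a difference of at least 0.5 were added by smallest p up to 8. From each list up to 8 members past the threshold or otherwise up to 4 with the smallest p could be named, as could all selenoproteins, Ins1, Ins2 and the sex-linked genes. Trsp, its targeted gene, had 0 probes. Some list members are not reported here.

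The alternatives were normexp background correction with an offset of 50 on the median spot signals, quantile normalization, median scaling, the deposited value table, no filter, a filter requiring all 6 arrays, the mean of the probes of a gene, eBayes with trend and robust, a fit of only the 2 groups compared, a replicate block, a 2-fold minimum and leaving out each array in turn. A fit without an array leaves 1 array in its group, which is then assumed to vary like the others. A mean-signal column was not used here, since the files used hold the median. Slide and scan could not enter the comparisons with TrspFF: both TrspFF arrays share 1 slide and scan, and all 4 knockout arrays share another. Both comparisons with TrspFF use the same 2 control arrays, which were too few to split.

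The method was tested on simulated data with the spread of the arrays and 22862 genes. With 100 genes shifted by 1 (log2), the shares called were 43%, 44% and 49% for Trsp-RIPKO against TrspFF, Trsp-Ins1KO against TrspFF and Trsp-RIPKO against Trsp-Ins1KO. With a shift of 2 they were 83%, 79% and 79%, and false calls numbered 2, 8 and 10. A shift of 0.3 put into 1 list was called by camera in each comparison with 0 other lists, at adjusted p of 9.66e-28, 3.84e-29 and 4.63e-36. With an estimated correlation the adjusted p was 0.147, 0.0307 and 0.0906. Genes were drawn independently of each other, so the simulated lists hold no correlation between members. The simulation therefore cannot show how often camera calls lists of correlated genes falsely.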

Results

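Trsp encodes the transfer RNA that carries selenocysteine into selenoproteins, several of which remove peroxides. The arrays address what loss of Trsp under a Cre driver active in insulin-producing cells, and for RIP-Cre also in part of the hypothalamus, does to hypothalamic transcripts. No probe was named Trsp and the gene table held 0 entries of that name among 49997, so the deletion itself was not checked. The 75th percentile of processed signal lay between 1391 and 2136, 68.9% to 72.0% of probes were well above background on each array, and 0 probes were saturated. The Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on every array, and Kdm5d on all but 1 of the Trsp-RIPKO arrays. With 2 arrays per group the precision is low: the difference between replicate arrays had an SD of 0.51 (TrspFF), 0.41 (Trsp-RIPKO) and 0.44 (Trsp-Ins1KO) log2.

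The names Trsp-RIPKO and Trsp-Ins1KO are exchanged between the scanner files and the deposited value table. Across probes centred on their medians, each of the 6 table columns matched 1 scanner file at r = 0.999998 or above. The columns labelled Trsp-RIPKO matched the arrays labelled Trsp-Ins1KO and the reverse, while against the arrays of their own label r lay between -0.22 and -0.20. Both TrspFF columns matched their own arrays. The table medians were 0.03 and -0.01 (TrspFF), 0.05 and -0.01 (columns labelled Trsp-RIPKO), and -0.01 and -0.05 (columns labelled Trsp-Ins1KO). Group names here follow the scanner files. With the names of the value table, every result given for 1 knockout belongs to the other and each difference between the knockouts changes sign.

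**Figure D1:**
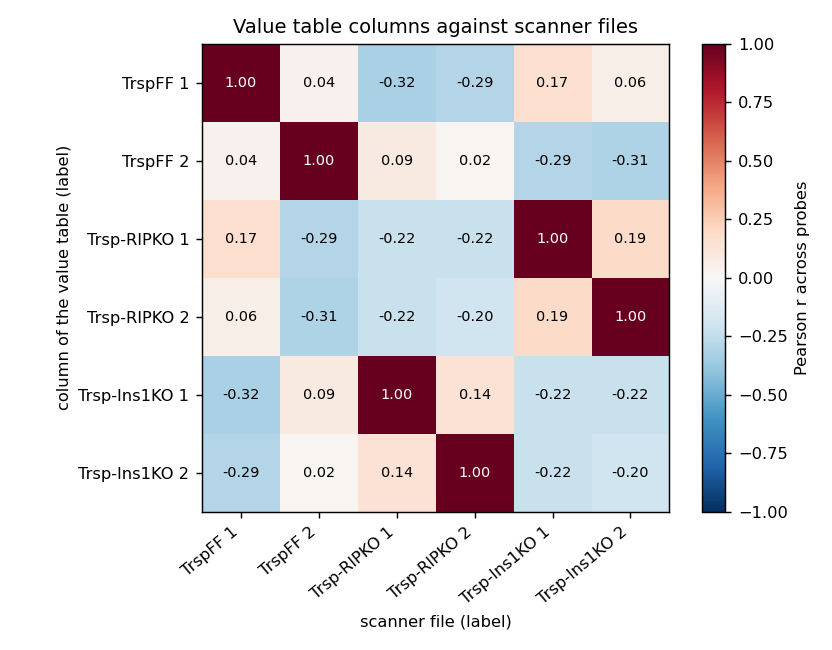
Pearson's r across probes between each column of the value table and each scanner file, after centring every probe on its median over the 6 arrays. The columns labelled Trsp-RIPKO match the arrays labelled Trsp-Ins1KO at r = 0.999998 and their own at -0.22 and -0.20.

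Against TrspFF, the arrays labelled Trsp-RIPKO had mainly lower transcripts: 357 of 22862 genes fell and 22 rose (limma, adjusted p under 0.05), and 213 of the falls and 5 of the rises were at least 2-fold. The adhesion receptor P-selectin, Selp, fell from -3.54 to -5.88 (difference -2.33, SE 0.0802, n = 2 per group, adjusted p = 0.0136). The bile acid transporter subunit Slc51b fell by 2.56 (SE 0.13, adjusted p = 0.0136) and Lingo1, a membrane protein of neurons and oligodendrocytes, fell by 2.61 (SE 0.15, adjusted p = 0.0168). Among rises, Mt3, a metallothionein of the brain, was 1.03 higher (SE 0.11, adjusted p = 0.0329) and Ceacam16 was 1.39 higher (SE 0.16, adjusted p = 0.0372). Genes with a usual symbol made up 31.7% of those changed (15 higher, 105 lower) against 66.0% of those tested.

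Other falls in the arrays labelled Trsp-RIPKO were Olfr715b (-2.13) and Rap1a (-2.50, well above background on 1 of the 2 Trsp-RIPKO arrays), at adjusted p of 0.0341 and 0.0498. Genes whose tested probe was not well above background on either Trsp-RIPKO array are given as bounds. Pgc was at least 4.17-fold lower (another of its probes was well above background there), Serpinb1c at least 3.18-fold, Adam24 at least 2.85-fold, the alcohol dehydrogenase gene Adh4 at least 2.47-fold, and Smg8, which acts in nonsense-mediated decay, at least 2.28-fold. Cdh17 and Lilra5 were at least 1.88-fold and 1.79-fold lower (adjusted p of these 7 from 0.0136 to 0.044). Smaller rises were Cenpi (0.99), C2cd4d (0.81), Snrnp70 (0.77, a protein of the U1 splicing particle), Tob2 (0.73), Ly6e (0.72), Fxyd7 (0.70), Pald1 (0.70), Palm (0.69) and Cabin1 (0.67), at adjusted p of 0.0329 to 0.0499. Plekhn1 was at least 1.11-fold higher, since it was not well above background on either TrspFF array. Its adjusted p of 0.0451 (limma) belongs to the fitted difference of 0.86 and not to this bound.

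The counts depend on which arrays enter the fit. Without TrspFF replicate 1, Trsp-RIPKO replicate 2, or either Trsp-Ins1KO array 0 genes passed in Trsp-RIPKO against TrspFF, without Trsp-RIPKO replicate 1 28 passed (0 higher), and without TrspFF replicate 2 495 (139 higher, 356 lower). The balance of directions moved too: 75.4% of calls were lower with trend and robust (193 higher, 592 lower) and 83.2% with normexp (71 and 352), against 94.2%. With the scanner files taken as 2 groups alone limma called 0 genes at a smallest adjusted p of 0.0603, with 4777 at unadjusted p under 0.05 (5476 with all 6 arrays). This fit, and those without a Trsp-Ins1KO array, leave every difference between Trsp-RIPKO and TrspFF as it was (Selp -2.33, Slc51b -2.56, Lingo1 -2.61); only the estimated spread and the degrees of freedom (3.91 against 4.87) change. Both TrspFF arrays sit on their own slide and scan, so batch and group cannot be told apart in either comparison with TrspFF.

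By camera, 3 of 38 lists passed in Trsp-RIPKO against TrspFF, all with adjusted p = 0.978 with an estimated correlation and 0 by fry (smallest adjusted p 0.604). Interferon response genes were higher (median 0.47, 21 of 22 positive, adjusted p = 0.000116), among them Isg15 (0.75) and Irf7 (0.65), neither past the threshold alone; leaving out 1 array moved the median between 0.31 (without Trsp-RIPKO replicate 2) and 0.68 (without Trsp-RIPKO replicate 1). Iigp1, an interferon-induced GTPase, went against its list and fell by 1.14 (SE 0.15, adjusted p = 0.0495), the single member to change over all genes and also when adjusted over the list alone (0.0173); with the mean of its probes its difference was 0.19. Immediate early genes were higher (median 0.43, 18 of 20 positive, adjusted p = 0.0161), with Npas4 at 1.05 and Fosb at 0.57; 0 members passed over all genes or adjusted over the list alone. That call ended without TrspFF replicate 1 (adjusted p = 0.258) or Trsp-RIPKO replicate 2 (0.0883), and with quantile normalization (0.0573) or median scaling (0.0597). Striatum markers were lower (median -0.45, 11 of 14 negative, adjusted p = 0.0161). The receptor gene Gpr6 fell by 0.78 (SE 0.078, adjusted p = 0.0294), and 5 members were lower when adjusted over the list alone, including Adora2a (-1.76), Drd1 (-0.92) and Rgs9 (-0.62). Without TrspFF replicate 2 the striatum call ended (adjusted p = 0.132).

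Lists tied to leptin and insulin action did not pass in Trsp-RIPKO against TrspFF. For leptin, insulin and melanocortin signalling adjusted p was 0.513; Pik3ca (-0.93) and Pcsk2 (0.49) passed when adjusted over the list alone (1 higher, 1 lower) and 0 over all genes. Feeding and energy-balance neuropeptides had adjusted p = 0.653, with Pmch at -0.88 and Adcyap1 at 0.73 past the threshold adjusted over the list alone and 0 members over all genes. NRF2 target genes had adjusted p = 0.909 (0 over all genes; Akr1b8 at -1.04 and Gclm at -0.54 lower adjusted over the list alone). For other antioxidant enzymes adjusted p was 0.428, with Mt3 the 1 member to rise by both adjustments. Inflammation (0.675) and the unfolded protein and integrated stress response (0.8) had 0 members past either. Other markers of tissue outside the hypothalamus and of vessels did not pass: choroid plexus had a median of -0.18 (adjusted p = 0.829), cortex, hippocampus and amygdala 0.56 (0.14), and endothelial cells 0.37 (0.169).

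Against TrspFF, the arrays labelled Trsp-Ins1KO had 361 genes lower and 55 higher of 22862 (limma, adjusted p under 0.05), 217 and 26 of them at least 2-fold. Lingo1 fell (difference -3.10, SE 0.15, n = 2 per group, adjusted p = 0.0123), Slc51b by 2.22 (SE 0.13, adjusted p = 0.0148) and Selp by 2.26 (SE 0.0802, adjusted p = 0.012; well above background on 1 of the 2 Trsp-Ins1KO arrays). Sdc4, a heparan sulfate proteoglycan of the cell surface, rose from -1.70 to 0.54 (difference 2.24, SE 0.11, adjusted p = 0.0123). Slpi, a secreted inhibitor of leukocyte proteases, rose by 1.07 (SE 0.11, adjusted p = 0.0309). Mt3 rose by 1.01 (SE 0.11, adjusted p = 0.0334), and Adora2a, the adenosine receptor of striatal neurons, fell by 2.41 (SE 0.29, adjusted p = 0.0375).

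Ttll2, a tubulin ligase-like gene, was at least 5.69-fold higher in the arrays labelled Trsp-Ins1KO, the forkhead gene Foxl1 at least 4.53-fold and Tmem154 at least 3.21-fold (adjusted p = 0.012, 0.0422 and 0.0117), none being well above background on either TrspFF array. Other rises were Mdm1 (1.29), Eif5b (1.22, a translation initiation factor), the glutathione transferase gene Gstm6 (1.16), Wtap (0.95, part of the RNA methylation complex), Methig1 (0.94) and Manbal (0.89), at adjusted p of 0.0232 to 0.0415. Ndfip2 fell by 1.96 and Olfr715b by 2.00 (adjusted p = 0.0326 and 0.0362). Bounds for genes not well above background on either Trsp-Ins1KO array were at least 2.82-fold lower for Serpinb1c, 2.53-fold for Adam24, 2.03-fold for Smg8, 1.67-fold for Cdh17, 1.59-fold for Lilra5 and 1.52-fold for the Polycomb gene Cbx7 (adjusted p from 0.0123 to 0.0484). Usual symbols made up 36.3% of the changed genes (30 higher, 121 lower). Without TrspFF replicate 2, either Trsp-RIPKO array or Trsp-Ins1KO replicate 1 0 genes passed in Trsp-Ins1KO against TrspFF, 1 passed without Trsp-Ins1KO replicate 2, and 511 without TrspFF replicate 1 (183 higher, 328 lower). Of the calls 86.8% were lower, against 54.6% with trend and robust (564 higher, 677 lower) and 67.1% with normexp (192 and 392). With the 2 groups alone limma called 0, with 4856 at unadjusted p under 0.05 against 5937 with all 6 arrays; there too, as without either Trsp-RIPKO array, the differences stay as they were and only the spread and degrees of freedom (3.84) change.

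By camera 16 lists passed in Trsp-Ins1KO against TrspFF, 9 higher and 7 lower, all with adjusted p = 0.697 with an estimated correlation and 0 by fry (smallest adjusted p 0.0907). Heat shock proteins were higher (median 0.31, 14 of 15 positive, adjusted p = 0.000651). Of these the chaperone gene Hsph1 rose by 0.76 (SE 0.0847, adjusted p = 0.0348), the 1 member past the threshold over all genes; 6 were higher adjusted over the list alone, among them Hspe1 (1.03) and Dnaja1 (0.35). Respiratory chain subunits (median 0.19, 40 of 46 positive, adjusted p = 0.000301) and proteasome subunits (median 0.20, 27 of 31, adjusted p = 0.00118) were higher with 0 members past either adjustment; Ndufa3 was at 0.68 and Psmb3 at 0.42. Quantile normalization left respiratory chain subunits at a median of 0.03 (adjusted p = 0.725) and proteasome subunits at 0.09 (0.245). The unfolded protein and integrated stress response was higher (median 0.22, adjusted p = 0.0108; Sdf2l1 0.89, Phgdh 0.38, 0 members past either adjustment). It ended with quantile normalization (adjusted p = 0.148) and without Trsp-Ins1KO replicate 2 (0.0976). Other antioxidant enzymes were higher (median 0.20, adjusted p = 0.0277), with Mt3 as the 1 gene over all genes and 8 higher and 1 lower adjusted over the list alone, including Sod1 (0.50), Mt1 (0.39) and catalase, Cat (-0.57). This ended with quantile normalization (adjusted p = 0.286), normexp (0.051), and without TrspFF replicate 2 (0.0534) or Trsp-Ins1KO replicate 2 (0.0811).

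Feeding and energy-balance neuropeptides were higher as a list in the arrays labelled Trsp-Ins1KO (median 0.38, 16 of 19 positive, adjusted p = 0.0108): Agrp 0.91, Pomc 0.88 and Adcyap1 0.81, with 0 past the threshold over all genes and Adcyap1 alone when adjusted over the list alone. Pomc was not particular to this knockout: its levels were 1.97 and 1.39 here, 1.57 and 1.62 in Trsp-RIPKO, and 0.85 and 0.75 in TrspFF. Without TrspFF replicate 1 adjusted p for the feeding list was 0.0538. Other hypothalamic neuropeptides were also higher (median 0.37, 15 of 19 positive, adjusted p = 0.0108; Avp 1.27, Oxt 0.94, Calca 0.74, 0 members past either adjustment). Hypothalamic nucleus transcription factors were higher at adjusted p = 0.0422 (median 0.34; Fezf1 0.69, Foxb1 0.49, 0 past either). In this same comparison markers of tissue outside the hypothalamus were lower: choroid plexus (median -2.01), meninges (-0.79), cortex, hippocampus and amygdala (-0.76) and striatum (-0.53). Endothelial (-0.35) and oligodendrocyte markers (-0.29) were lower as well. The call for these transcription factors ended without TrspFF replicate 2 (adjusted p = 0.202) or Trsp-Ins1KO replicate 2 (0.0976), with normexp (0.0947) and with median scaling (0.102). Leptin, insulin and melanocortin signalling did not pass (adjusted p = 0.31), though Pik3ca, a catalytic subunit of phosphoinositide kinase, fell by 0.97 (SE 0.13, adjusted p = 0.0469). Adjusted over the list alone Pik3ca and Pcsk2 (0.59) passed, 1 lower and 1 higher. NRF2 target genes (adjusted p = 0.188) held 1 member that rose by both adjustments, Gstm6. In the interferon response list (adjusted p = 0.242) Iigp1 fell by 1.31 (SE 0.15, adjusted p = 0.0366), and adjusted over the list alone 1 member was lower and 1 higher.

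Choroid plexus, cortex and meningeal markers were lower in the arrays labelled Trsp-Ins1KO, and 1 array carried most of it; thalamus markers (median 0.18, adjusted p = 0.406) and pituitary markers (0.32, 0.481) did not pass. Choroid plexus markers had a median of -2.01 (16 of 16 negative, adjusted p = 0.000651), with Sostdc1 at -2.21 and Steap1 at -1.76. Their array means were 0.91 and 0.40 (TrspFF), 0.39 and 0.57 (Trsp-RIPKO), 0.03 (Trsp-Ins1KO replicate 1) and -2.31 (replicate 2), and leaving out 1 array moved the median between -3.14 and -0.62, the latter without Trsp-Ins1KO replicate 2. Cortex, hippocampus and amygdala markers (median -0.76, adjusted p = 0.00631; Slc17a7 -0.86, Nptx1 -0.56) and meningeal and fibroblast markers (median -0.79, adjusted p = 0.00631; Igf2 -1.51, Fn1 -0.83) went to -0.05 (adjusted p = 0.305) and -0.09 (0.502) without Trsp-Ins1KO replicate 2. The cortex call also ended without TrspFF replicate 2 (adjusted p = 0.156) and the meningeal call without TrspFF replicate 1 (0.133). Each of these lists had 0 members past the threshold over all genes or adjusted over the list alone. The transthyretin gene Ttr, strongly expressed in choroid plexus, had levels of 5.39 and -0.95 on the Trsp-Ins1KO arrays and 5.56 to 6.31 on the others.

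Striatum, vascular and oligodendrocyte markers were lower as well, each at adjusted p = 0.00631. In the striatum list (median -0.53) Adora2a and Gpr6 (-0.58, adjusted p = 0.0469) fell, and adjusted over the list alone 7 were lower and 1 higher, with Drd1 at -1.20; without Trsp-Ins1KO replicate 1 adjusted p was 0.0575. Endothelial markers had a median of -0.35 (14 of 14 negative; Esam -0.87, Cdh5 -0.47; 0 members past either adjustment) and pericyte and smooth muscle markers -0.45 (0 over all genes, Acta2 at -0.72 and Myh11 at -0.89 adjusted over the list alone, Myh11 well above background on 1 of the 2 Trsp-Ins1KO arrays). Both calls ended without TrspFF replicate 2. Leaving out 1 array moved the endothelial median between -0.59 and -0.22 and the pericyte and smooth muscle median between -0.53 and -0.27. Oligodendrocyte markers had a median of -0.29 (0 over all genes, Ermn at -1.02 lower adjusted over the list alone, Mbp -0.51). This call ended without TrspFF replicate 2 (median -0.09) or Trsp-Ins1KO replicate 1 (-0.17), and leaving out 1 array moved the median between -0.52 and -0.09.

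**Figure D2:**
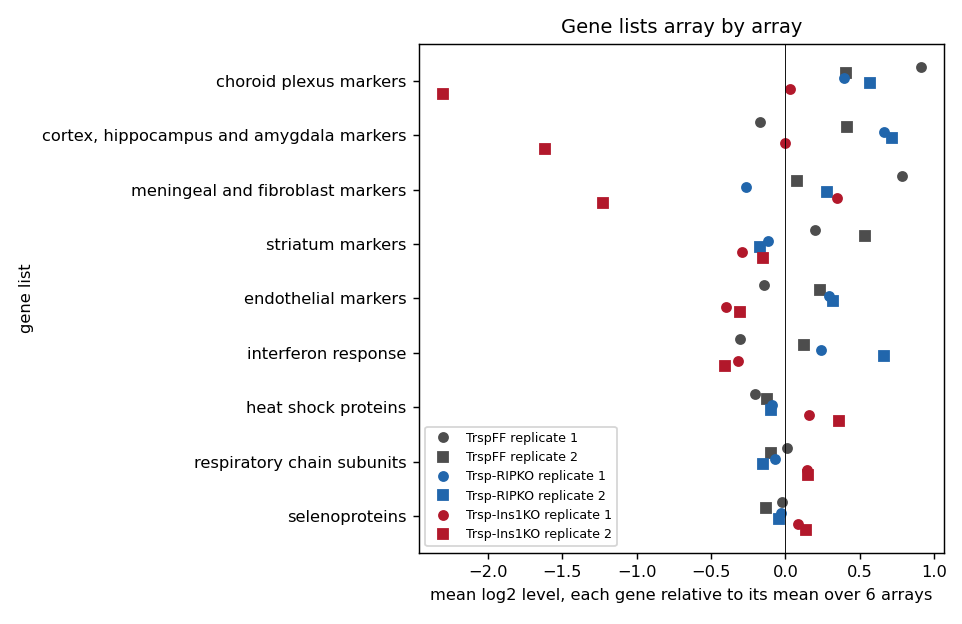
Mean log2 level of the members of selected lists on each array, each gene relative to its mean over the 6 arrays. Choroid plexus markers are at -2.31 and cortex, hippocampus and amygdala markers at -1.62 on Trsp-Ins1KO replicate 2, against 0.03 and -0.0047 on replicate 1.

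Of 24 selenoproteins 23 were measured (all but Dio3), and in limma 0 changed in any comparison, over all genes or adjusted over the list alone. At unadjusted p under 0.05 were 6 in Trsp-RIPKO against TrspFF and 8 in Trsp-Ins1KO against TrspFF. Nearest to the threshold were Gpx2, a glutathione peroxidase, at 0.38 in Trsp-RIPKO (SE 0.0828, n = 2 per group, adjusted p = 0.0957) and Selenok, of the endoplasmic reticulum, at 0.40 in Trsp-Ins1KO (SE 0.0805, adjusted p = 0.0836). Selenok passed with normexp (0.50, adjusted p = 0.0475) and with trend and robust (adjusted p = 0.0375). As a list selenoproteins were higher in Trsp-Ins1KO (median 0.17, 19 of 23 positive, adjusted p = 0.0107, but 0.697 with an estimated correlation and 0.104 by fry), where median scaling turns Selenop and quantile normalization turns Selenom and Selenof to the other side of 0. The call ended with quantile normalization (adjusted p = 0.156) and without Trsp-Ins1KO replicate 2 (0.0519). In Trsp-RIPKO the median was 0.08 (16 of 23 positive, also Msrb1 and Txnrd2 with median scaling; adjusted p = 0.468). Gpx4 was at 0.08 and 0.22 and Gpx1 at 0.11 and 0.23 in Trsp-RIPKO and Trsp-Ins1KO (Gpx1 below 0 in Trsp-RIPKO with normexp). Gpx3 in Trsp-Ins1KO was at 1.03 (SE 0.34, adjusted p = 0.153), and at 1.54 with adjusted p = 0.0322 without TrspFF replicate 1. Selenop, the selenium carrier, was at -0.42 in Trsp-RIPKO (SE 0.13, adjusted p = 0.163).

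In the selenocysteine synthesis and insertion list (12 measured, adjusted p = 0.8 and 0.848) Secisbp2l, related to the protein that binds selenocysteine insertion elements, was at -1.15 in Trsp-RIPKO (SE 0.16, adjusted p = 0.051) and fell by 1.14 in Trsp-Ins1KO (SE 0.16, adjusted p = 0.0496). Adjusted over the list alone it was lower and Eefsec, the elongation factor for selenocysteine, higher (0.49 and 0.43) in both comparisons. Ins1, the locus of 1 of the drivers, was at -0.24 in Trsp-RIPKO and -1.42 in Trsp-Ins1KO (SE 0.59, adjusted p = 0.824 and 0.212), and Ins2 at -0.20 and -0.55 (adjusted p = 0.516 and 0.152). Without TrspFF replicate 1 the Trsp-RIPKO differences of Ins1 and Ins2 were 0.25 and 0.03. The arrays labelled Trsp-Ins1KO had Ins1 levels of -4.59 and -6.02; the Ins1 difference was -0.71 without Trsp-Ins1KO replicate 2, -2.13 without replicate 1 and -0.93 without TrspFF replicate 1, and Ins2 was at -0.31 without TrspFF replicate 1.

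**Figure D3:**
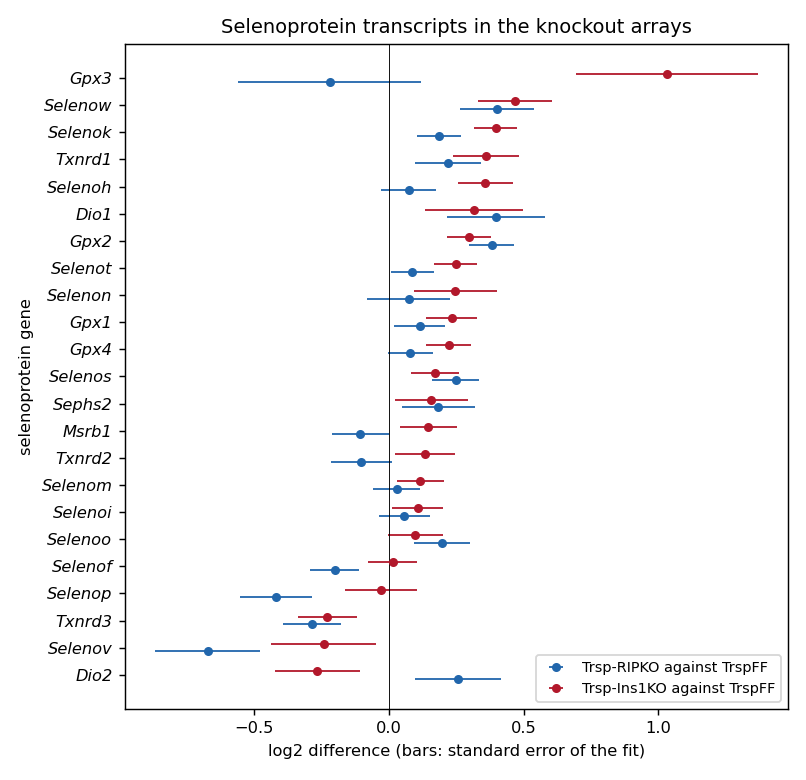
Log2 difference from TrspFF of each measured selenoprotein in the arrays labelled Trsp-RIPKO and Trsp-Ins1KO, with standard errors. Of the 23 genes 0 passed the threshold in limma, and the medians are 0.08 and 0.17.

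Between the knockouts, 4 genes differed among 22862 (limma, adjusted p under 0.05), all higher in the arrays labelled Trsp-Ins1KO and all more than 2-fold. Sdc4 was at -2.21 in Trsp-RIPKO and 0.54 in Trsp-Ins1KO (difference -2.75, SE 0.11, n = 2 per group, adjusted p = 0.0194) and Slpi at -5.90 and -3.58 (difference -2.32, SE 0.11, adjusted p = 0.0323). Ttll2 was at least 6.47-fold lower in Trsp-RIPKO (adjusted p = 0.0194) and Tmem154 at least 3.65-fold (adjusted p = 0.00933), as neither was well above background on either Trsp-RIPKO array. On Trsp-Ins1KO arrays Tmem154 had levels of -4.57 and -4.62, against -8.90 to -8.54 on the others. Further genes did not pass: Foxl1 was at least 5.15-fold lower (adjusted p = 0.256), Dera -1.14 and Ceacam16 1.77 (both 0.201), Zbtb17 at least 1.26-fold higher (0.187), Dusp5 at least 1.63-fold higher (0.263), Cenpi 1.11 (well above background on 1 of the 2 Trsp-Ins1KO arrays) and Itga9 -0.95 (both 0.256).

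All 4 knockout arrays share 1 slide and scan, and a fit of these arrays alone called 318 genes (162 higher, 156 lower), the 4 genes among them, and 15 lists. Of the further genes named above, Ceacam16 (limma, adjusted p = 0.0381), Zbtb17 (0.04), Dera (0.0439) and Dusp5 (0.048) passed in that fit. Leaving out either TrspFF array gives that same fit and count, since 1 array adds no spread. Without Trsp-RIPKO replicate 1, 22 genes passed, 2 of the 4 among them. Without Trsp-RIPKO replicate 2 or Trsp-Ins1KO replicate 1 0 passed, and without Trsp-Ins1KO replicate 2 1 gene passed, which is none of the 4 and is higher in Trsp-RIPKO. At unadjusted p under 0.05 there were 4215.

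**Figure D4:**
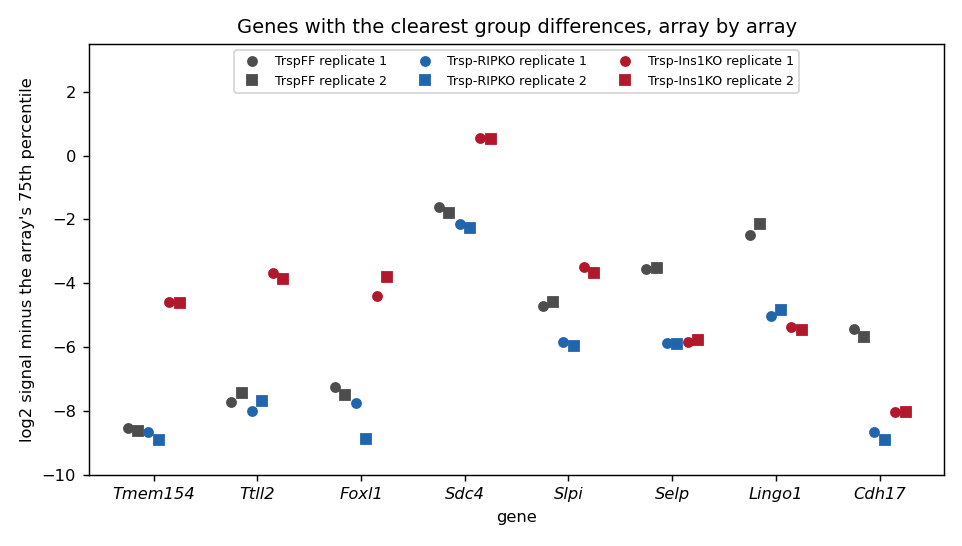
Log2 level on each array, relative to the 75th percentile of the array, of named genes in the 3 genotypes. Sdc4 is at 0.56 and 0.53 on the Trsp-Ins1KO arrays and between -2.28 and -1.60 on the other 4.

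By camera 20 lists differed between the knockouts, 10 in each direction, with 0 members past the threshold over all genes; with an estimated correlation adjusted p was 0.481 except where given, and fry called 0 (smallest adjusted p 0.0697). Interferon response genes were higher in the arrays labelled Trsp-RIPKO (median 0.70, 21 of 22 positive, adjusted p = 9.66e-09), 12 of them adjusted over the list alone: Gbp3 1.39, Irf7 1.10 (well above background on 1 of the 2 Trsp-Ins1KO arrays) and Isg15 0.90. Leaving out 1 array moved the interferon median between 0.41 (without Trsp-RIPKO replicate 2) and 1.02 (without Trsp-RIPKO replicate 1). The TrspFF arrays were spread along the same lists: interferon means were -0.31 and 0.13 (Trsp-RIPKO 0.24 and 0.66, Trsp-Ins1KO -0.32 and -0.41), endothelial means -0.14 and 0.23, oligodendrocyte means -0.11 and 0.31, and cortex means -0.17 and 0.42 on TrspFF replicates 1 and 2. Across genes TrspFF replicate 1 correlated most with Trsp-Ins1KO replicate 1 (r = 0.988) and TrspFF replicate 2 with Trsp-RIPKO replicate 1 (r = 0.991), above the r of 0.986 between them; genes are not independent replicates. Immediate early genes (median 0.40, adjusted p = 0.000947, 0.5 with an estimated correlation; Egr4 1.01, Klf2 0.61) and the p53 and DNA damage response (median 0.16, adjusted p = 0.0207; Gadd45a 0.91) were higher with 0 adjusted over the list alone. The call for immediate early genes ended without Trsp-Ins1KO replicate 2 (median 0.16, adjusted p = 0.0767; 0.62 without replicate 1), that for the p53 response without Trsp-RIPKO replicate 2 (median 0.064, 0.103) and with the mean of probes (0.0547).

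Lower in Trsp-RIPKO than in Trsp-Ins1KO were respiratory chain subunits (median -0.26, 45 of 46 negative, adjusted p = 4.49e-09; Ndufb6 -0.39, Uqcrb -0.34) and proteasome subunits (median -0.13, 29 of 31, adjusted p = 0.000744; Psmd1 -0.37), with 0 members adjusted over the list alone. With quantile normalization proteasome subunits had a median of -0.034 and an adjusted p of 0.154 (camera). Heat shock proteins were lower (median -0.26, 14 of 15, adjusted p = 0.000762), with the mitochondrial chaperonin gene Hspe1 (-1.24) the 1 member adjusted over the list alone. NRF2 target genes (median -0.16, adjusted p = 0.0262; Gstm6 -0.65) and the unfolded protein and integrated stress response (median -0.16, adjusted p = 0.0248; Pdia6 -0.44) were lower with 0 adjusted over the list alone. Both had adjusted p = 0.065 with quantile normalization. Without Trsp-RIPKO replicate 1 the adjusted p was 0.312 for NRF2 target genes and 0.0995 for the unfolded protein response. The NRF2 call also ended without Trsp-Ins1KO replicate 1 (adjusted p = 0.0833) and with no filter (0.0871), and the unfolded protein call without Trsp-Ins1KO replicate 2 (0.214) and on the 4 knockout arrays alone (0.0512).

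Of the neuropeptide and neuron lists, 3 were lower in Trsp-RIPKO than in Trsp-Ins1KO and the others did not pass. Hypothalamic nucleus transcription factors had a median of -0.43 (-0.39 with genes at their bounds; 18 of 19 negative, adjusted p = 0.000103; Hmx2 -1.05 and Isl1 -0.63 the 2 members adjusted over the list alone). Other hypothalamic neuropeptides had a median of -0.43 (adjusted p = 0.037), with Tac1 (-0.70), Calca (-0.64) and Prok2 (-1.23) lower and Cort (1.87) higher adjusted over the list alone. GABA neuron markers had a median of -0.33 (adjusted p = 0.0238), with Dlx5 (-0.49) and Isl1 lower adjusted over the list alone. On the 4 knockout arrays alone, the fit that also results without either TrspFF array, adjusted p was 0.0875 for the other neuropeptides and 0.0531 for GABA markers. The neuropeptide call also ended without Trsp-RIPKO replicate 1 (adjusted p = 0.0853), without Trsp-Ins1KO replicate 2 (0.0536) and with a filter on all arrays (0.0771). The GABA call ended without Trsp-RIPKO replicate 2 (0.0869) or Trsp-Ins1KO replicate 2 (0.0662). Feeding and energy-balance neuropeptides had adjusted p = 0.094; Pmch, which encodes melanin-concentrating hormone, was at -1.25 and the 1 member adjusted over the list alone, and Pomc was at -0.08 (0.21 without Trsp-Ins1KO replicate 1). Selenoproteins had a median of -0.14 (adjusted p = 0.1).

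Markers of other cells and of tissue outside the hypothalamus also separated the knockouts. Endothelial markers were higher in Trsp-RIPKO (median 0.73, adjusted p = 8.08e-07), 10 adjusted over the list alone, with Slco1a4 at 1.26 and Cdh5 at 0.90. Pericyte and smooth muscle markers were higher (median 0.48, adjusted p = 3.33e-05; 2 adjusted over the list alone, Acta2 0.81 and Myh11 0.71), as were oligodendrocyte markers (median 0.35, 16 of 16 positive, adjusted p = 3.33e-05; 0 adjusted over the list alone). Cortex, hippocampus and amygdala markers (median 1.52, 17 of 17 positive, adjusted p = 1.01e-07; Slc17a7 1.47) and choroid plexus markers (median 1.90, adjusted p = 9.19e-05; Steap1 1.88) were higher with 0 adjusted over the list alone. These 5 calls held without each of the 6 arrays in turn, but sizes moved. Without Trsp-Ins1KO replicate 2 the choroid plexus median was 0.43 and the cortex median 0.67 (3.07 and 2.30 without replicate 1), and without Trsp-Ins1KO replicate 1 the oligodendrocyte median was 0.20. The interferon, transcription factor, heat shock, respiratory chain and proteasome calls also held without each array.

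Meningeal and fibroblast markers were higher in Trsp-RIPKO (median 0.50, adjusted p = 0.0262, 0.685 with an estimated correlation; Fn1 0.63; 0 adjusted over the list alone), but had a median of -0.25 without Trsp-Ins1KO replicate 2 (adjusted p = 0.336). Tanycyte markers were higher (median 0.52, adjusted p = 0.0262; adjusted over the list alone Nes at 0.54 higher and Gpr50 at -0.90 lower, Gpr50 well above background on 1 of the 2 Trsp-RIPKO arrays). Both had adjusted p = 0.281 without Trsp-RIPKO replicate 2, and 0.0531 (meningeal) and 0.0601 (tanycyte) without either TrspFF array; without Trsp-Ins1KO replicate 2 the tanycyte value was 0.0507 (median 0.16). Quantile normalization gave 0.0668 and 0.065. Ependymal cell markers were lower (median -0.69, adjusted p = 0.00546, 0.559 with an estimated correlation; Tekt4 -0.88), with a median of -0.30 and adjusted p = 0.202 without Trsp-RIPKO replicate 1. Astrocyte markers were lower (median -0.23, adjusted p = 0.0238; Aldoc -0.40) and ended without Trsp-RIPKO replicate 1 (0.0501) or Trsp-Ins1KO replicate 2 (0.0662) and with quantile normalization (0.0683); both lists had 0 members adjusted over the list alone.

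The comparisons with TrspFF shared many genes. Lower in both knockouts were 266 genes, of 357 and 361, 5 were higher in both and 1 had opposite calls: Slpi, lower in Trsp-RIPKO (-1.25, adjusted p = 0.0243) and higher in Trsp-Ins1KO (1.07). Named genes lower in both are Selp, Lingo1, Slc51b, Smg8, Adam24, Serpinb1c, Cdh17, Lilra5, Olfr715b, Gpr6 and Iigp1, and Mt3 is higher in both. The median differences of the 266 were -1.16 in Trsp-RIPKO and -1.20 in Trsp-Ins1KO, and 72 had a usual symbol. Between the knockouts 258 of them differed by less than 0.5. Their choice as lower in both favours this, and the share among all tested genes was not counted. Both comparisons use the same 2 control arrays, which alone relates them. Simulated values are means of 20 draws with shared controls and no true difference. The correlation of differences across all genes was 0.32 (0.50 simulated), the covariance 0.0746 (0.0353 simulated), and the share with the same sign 67.4% (66.8% simulated). Genes are not independent replicates. The largest number of genes called in the same direction in both comparisons in any draw was 0, against 266 lower and 5 higher here. The draws hold independent noise for each gene, where hardly any gene can pass, so that 0 follows largely from their design. They do not separate genotype from slide and scan or from shifts that many genes share on the control arrays.

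**Figure D5:**
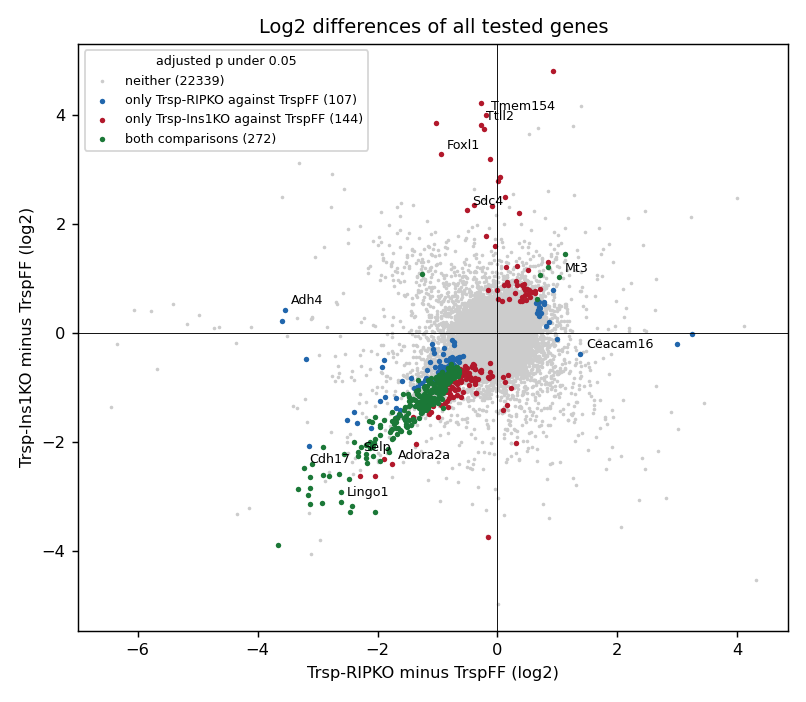
Log2 difference from TrspFF of each tested gene in the arrays labelled Trsp-RIPKO (horizontal) and Trsp-Ins1KO (vertical). Of the genes called, 266 are lower and 5 higher in both.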

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

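All tests in this part were chosen after the results were seen, except the test of other probes for the 4 genes that differ between the knockouts, which was written before.

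A test of the difference between the arrays labelled Trsp-RIPKO and Trsp-Ins1KO singled out 4 genes, each higher in Trsp-Ins1KO: Sdc4 (-2.75), Slpi (-2.32), Tmem154 (fitted -4.19) and Ttll2 (fitted -4.08), the last 2 not well above background in Trsp-RIPKO and so bounded at 3.65-fold and 6.47-fold. Sdc4 and Slpi lie on chromosome 2 with 2 tested genes between them, Matn4 at 0.03 and Rbpjl at -0.40, while Tmem154 lies on chromosome 3 and Ttll2 on chromosome 17. The 32 nearest tested genes had a median absolute difference of 0.27, at the 97.8th percentile of 1000 random windows. Of them 4 had p under 0.05 (limma), where 5.75 would at the share of all genes. Absolute differences cannot show a shared direction, so this test does not decide whether a segment of chromosome shifts as a whole. The signed differences of these neighbours ran both ways, from -0.85 (Fndc1, near Ttll2) to 1.06 (Kcns1, near Sdc4). They argue against a segment that shifts as a whole by the size seen in the 4 genes. A smaller shared shift stays open. Signal of single probes stays open too, since 0 of the 4 genes had another kept probe, and a further Tmem154 probe that is not well above background differed by -0.18. The genotype, which includes the Cre driver and the region inherited with it, also stays open and was not tested. It may apply to either knockout, because the labels of the scanner files and of the value table disagree. A single inherited region cannot hold all 4 genes, which lie on chromosomes 2, 3 and 17.

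Lower in both knockouts than in TrspFF were 266 genes, with median differences of -1.16 and -1.20. The tables argue against a shift of all signals of like brightness, since 4558 other genes nearest in level had a median difference of -0.0075. Slide and scan cannot be told apart from genotype here, since 0 slides hold both TrspFF and knockout arrays. Within genotype, loss of Trsp and presence of a Cre driver cannot be told apart either, as no group carries Cre without floxed alleles. Part of the overlap may also come from the shared TrspFF arrays, which were too few to split. Draws with shared controls and no true difference gave at most 0 shared calls. They hold independent noise for each gene, where hardly any gene can pass the threshold. They therefore do not decide how much the shared arrays contribute. Signal of single probes stays open: 27 other kept probes of 23 of these genes had a median of -0.15 (bootstrap 95% interval -0.49 to 0.0040, 2000 draws), against -1.02 for the tested probes of those genes and -0.03 for other probes of the remaining genes. Of the 27, 9 fell by at least 0.5 times the difference of the tested probe and 13 lay above -0.1.

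Choroid plexus and cortex markers were far lower on Trsp-Ins1KO replicate 2 than on any other array. Tissue present in 1 sample and not in another stays open: without that array the mean difference of choroid plexus markers from TrspFF was -0.63, against -1.79 with all arrays and -2.96 without replicate 1, but the array was picked for its low markers, so this follows from the gap already seen and decides nothing. Without that array cortex, hippocampus and amygdala markers went from -0.93 to -0.13 and meningeal and fibroblast markers from -0.87 to -0.08. Without replicate 1 they were at -1.74 and -1.66. The gap of 2.34 between the Trsp-Ins1KO arrays, against 0.50 in TrspFF and 0.17 in Trsp-RIPKO, is not what a shared genotype alone would give. For the remaining difference the genotype stays open. Trsp-Ins1KO replicate 1 (0.03) also lies below the lower TrspFF array (0.40), but so, barely, does Trsp-RIPKO replicate 1 (0.39). With a gap of 0.50 between the TrspFF arrays, 1 array cannot decide this.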

How the results depend on the processing

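All alternatives in this part were planned and none was chosen after a result was seen. With 4.87 degrees of freedom, the smallest adjusted p was 0.0136, 0.0117 and 0.00933 in the 3 comparisons. Between 68.9% and 72.0% of probes were well above background, and fainter transcripts could not be compared. For Trsp-RIPKO against TrspFF, apart from the value table and single arrays left out, 473 of 610 values of 69 named genes kept direction and side of the threshold, 110 fell short, 18 newly passed and 9 changed sign. For Trsp-Ins1KO against TrspFF these were 600 of 736 (83 genes), 104, 25 and 7, and between the knockouts 352 of 371 (42 genes), 13, 6 and 0. Only genes past the threshold in the reported fit could fall short: 26 of the 69, 29 of the 83 and 4 of the 42. Many of the kept values therefore belong to genes that were never called, and the kept share does not measure how stable the calls were. Settings not listed here left the total counts within 1.5 times of those reported, but like counts did not mean the same genes. Normexp called 423 genes in Trsp-RIPKO against TrspFF, 219 of them among the 379 reported. In Trsp-Ins1KO against TrspFF it called 584, with 262 among the 416 reported. Counts of higher genes moved further: against 22 in Trsp-RIPKO and 55 in Trsp-Ins1KO, normexp gave 71 and 192, the filter on all arrays 56 and 99, quantile normalization 34 and 70, and trend and robust 193 and 564 (592 and 677 lower). Blocking by slide was not run: slide follows TrspFF and is shared by all knockout arrays. Normexp used median spot signals, as no mean-signal column was used here. Unless said, the cause was not tested.

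Leaving out 1 array gave 0 to 495 genes and 2 to 4 lists for Trsp-RIPKO against TrspFF, 0 to 511 genes and 10 to 17 lists for Trsp-Ins1KO against TrspFF, and 0 to 318 genes and 15 to 24 lists between the knockouts; the lone array of a group is then assumed to vary like the others. With TrspFF left out the knockouts differed in 318 genes, by construction the same with 1 or both TrspFF arrays removed. Fits of the 2 groups alone gave 0 genes for Trsp-RIPKO (4777 at unadjusted p under 0.05) and 0 for Trsp-Ins1KO (4856) against TrspFF in limma, with fewer degrees of freedom. With no filter 0 (5016 at unadjusted p under 0.05), 25 and 1 genes passed in the 3 comparisons. Trend and robust gave 785, 1241 and 1. Median scaling gave 224 for Trsp-RIPKO, with the median difference of all genes in Trsp-Ins1KO at 0.11, against 0.02 with the 75th percentile. Normexp gave 1 gene between the knockouts, and the filter on all arrays 2. At least 2-fold were 218 and 243 genes against TrspFF, fewer by construction. Camera with an estimated correlation and fry each called 0 lists in every comparison, with smallest unadjusted p of 0.168, 0.0501 and 0.0439 by the former. The value table gave 16 lists for Trsp-RIPKO and 3 for Trsp-Ins1KO, since its labels exchange these groups.

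Replicate numbers do not pair the arrays: deviations from the group mean correlated across genes at -0.03, 0.09 and -0.02 between groups. A replicate block called 0 genes in each comparison (limma; 5457, 5746 and 4212 at unadjusted p under 0.05) and 3, 15 and 17 lists. With the block the call for hypothalamic nucleus transcription factors in Trsp-Ins1KO against TrspFF ended (adjusted p = 0.0574), as did those between the knockouts for NRF2 target genes (0.0511), other hypothalamic neuropeptides (0.0527) and the unfolded protein and integrated stress response (0.0662).

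Signs that changed in Trsp-RIPKO against TrspFF were, with normexp, Selenoo -0.0053, Gpx1 -0.079 and Selenon -0.046; with median scaling, Msrb1 0.0019 and Txnrd2 0.006. With the mean of probes, Dio1 was -0.24, Selenot -0.14, Selenon -0.27 and Iigp1 0.19. Leaving out 1 array at a time moved Gpx3 from -0.73 to 0.29, Ins1 from -0.73 to 0.25 and Ins2 from -0.44 to 0.033 (each highest without TrspFF replicate 1; Ins1 0.043 without Trsp-RIPKO replicate 1). The ranges were -0.025 to 0.17 for Selenoh, -0.078 to 0.22 for Selenon and -0.0028 to 0.061 for Selenom (each lowest without TrspFF replicate 2), and -0.21 to 0.0089 for Txnrd2 (highest without Trsp-RIPKO replicate 2). In Trsp-Ins1KO against TrspFF they were, with normexp, Selenoo -0.088 and Selenop 0.060, with quantile normalization, Selenom -0.011 and Selenof -0.080, and with median scaling, Selenop 0.056. With the mean of probes, Dio1 was -0.11 and Selenon -0.051. Leaving out 1 array at a time, Selenop ranged from -0.18 to 0.12 (highest without TrspFF replicate 1; 0.020 without Trsp-Ins1KO replicate 1) and Selenof from -0.025 (without Trsp-Ins1KO replicate 1) to 0.053. Between the knockouts Pomc ranged from -0.37 to 0.21, highest without Trsp-Ins1KO replicate 1.

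The value table turned further signs because its labels exchange the knockouts. Against TrspFF its columns labelled Trsp-RIPKO gave Ceacam16 -0.38, Cenpi -0.12, Adh4 0.42, Selenof 0.014, Dio2 -0.27, Msrb1 0.15, Txnrd2 0.13, Gpx3 1.03, Pmch 0.37 and Isg15 -0.15. Those labelled Trsp-Ins1KO gave Tmem154 -0.19, Ttll2 -0.28, Foxl1 -0.94, Sdc4 -0.51, Slpi -1.25, Gpx3 -0.22, Dio2 0.26, Msrb1 -0.11, Txnrd2 -0.10, Selenof -0.20, Hspe1 -0.20, Cdh5 0.42, Acta2 0.090, Slc17a7 0.61 and Steap1 0.12. Between the columns labelled Trsp-RIPKO and Trsp-Ins1KO all 42 named genes changed sign: Zbtb17 -0.94, Ceacam16 -1.77, Cenpi -1.11, Dusp5 -1.49, Jmjd4 -1.20, Afap1l1 -1.03, Flvcr2 -0.91, Metap1d -0.86, Tmem154 4.19, Ttll2 4.08, Sdc4 2.75, Slpi 2.32, Dera 1.15, Foxl1 4.21, Zic5 0.79, Itga9 0.95, Sephs1 -0.40, Gstm6 0.65, Prdx4 0.42, Pmch 1.25, Tac1 0.71, Pcsk1 0.57, Irf7 -1.10, Pdia6 0.44, Gadd45a -0.91, Hspe1 1.24, Ier5 -1.49, Ndufb6 0.39, Psmd1 0.37, Dlx5 0.50, Isl1 0.64, Aldoc 0.40, Nes -0.54, Tekt4 0.88, Cdh5 -0.90, Acta2 -0.81, Slc17a7 -1.47, Steap1 -1.88, Fn1 -0.63, Ins1 -1.18, Ins2 -0.34 and Pomc 0.084. In this paragraph the values of Tmem154, Ttll2, Foxl1, Zbtb17 and Dusp5 are fitted differences and not measured sizes. By the scanner labels Tmem154, Ttll2 and Foxl1 were not well above background on any TrspFF or Trsp-RIPKO array, and Zbtb17 and Dusp5 on either Trsp-Ins1KO array. The differences between the knockouts are bounded at 3.65-fold (Tmem154), 6.47-fold (Ttll2), 5.15-fold (Foxl1), 1.26-fold (Zbtb17) and 1.63-fold (Dusp5).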

Other observations

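The genes, lists and correlations in this part were chosen after their values were seen, and no test was run on the array patterns given here. Between groups, camera had called neither the pituitary nor the dopamine and histamine neuron markers in any comparison (smallest adjusted p 0.231 and 0.909). Some transcripts were high on TrspFF replicate 1 alone or together with the arrays labelled Trsp-Ins1KO. Cga, the shared subunit of pituitary glycoprotein hormones, had a level of -1.78 on TrspFF replicate 1 and between -8.04 and -5.88 on the other 5 arrays. Pituitary markers had a mean of 0.70 there against -0.24 to -0.05 elsewhere. That mean is over 6 measured genes including Cga, whose gap is large enough to carry it, so it is no separate sign. The hormone genes Gh, Prl, Fshb and Tshb were not measured. Ccr6, a chemokine receptor gene, was at -1.92 on TrspFF replicate 1 and -2.16 and -1.90 on the Trsp-Ins1KO arrays, against -7.40 on TrspFF replicate 2 and -7.59 and -6.86 on the Trsp-RIPKO arrays. The fast-muscle troponin genes Tnni2 and Tnnt3 split the same way: Tnni2 was at -1.04, -0.48 and -0.60 against -3.68 to -3.45, and Tnnt3 at -2.99, -2.59 and -2.71 against -6.40 to -5.57.

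Across all tested genes Trsp-RIPKO arrays correlated at r = 0.991 with each other and Trsp-Ins1KO arrays at 0.990; genes are not independent replicates. Dopamine and histamine neuron markers differed between the Trsp-Ins1KO arrays, with means of -0.63 and 0.58.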
